A study of Mus musculus with 17 samples.

How the data were processed

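RNA from 17 cultures of mouse embryonic stem (ES) cells and their derivatives was hybridised to 17 Affymetrix expression arrays, with 1 array per condition. Per the labels' protocols, ES cells were differentiated, cells carrying the VEGF receptor Flk1 were purified by magnetic sorting, and these were replated with or without vascular endothelial growth factor (VEGF). Cells in the knockdown arrays received small interfering RNA (siRNA) under VEGF. Total RNA was collected with a column kit and labelled with biotin, per the labels' protocols. The siRNA amount behind the arrays labelled si-control*4 and si-Mix and the duration of VEGF in the siRNA arrays are not given in the sources used here.

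The deposited values are 1 intensity per probe set and array, on a linear scale. Per the submitters' processing notes the tool was GCOS, with no version or settings given. The values show that each array was scaled to a common level: after leaving out 2% of probe sets at each end, the mean signal rounds to 499.8 on all 17 arrays. The lowest value is 1 and the highest 80983.5. The other percentiles differ between arrays, so no quantile normalization had been applied. No scanner files were analysed here, so neither background correction nor probe summary was repeated.

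Of 45101 probe sets, 64 control probe sets were left out and 45037 were used. The platform annotation gave 34945 of them 1 gene symbol and 932 several, and did not list 9160; probe sets with several genes or none name no gene here. For 34741 of the probe sets with 1 symbol, the gene identifier was found in the current mouse gene table. This gave 18193 genes, of which 9010 had more than 1 probe set; the probe set with the highest mean over the 17 arrays stood for the gene. No genome build is given with the files, so no coordinates are given.

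Values below a floor of 45.8, the 40th percentile of all values pooled, were raised to it, and log2 was taken. A difference against an array at the floor is a lower bound and is written as "at least". Array quality was described by the percentage of probe sets above the floor, the 3'/5' signal ratios of the actin and Gapdh control probe sets, and the spike controls. Spike controls and 18S ribosomal RNA probe sets separated the 7 siRNA arrays from the other 10, so no comparison was made across these sets. With arrays, the number of arrays limits the precision, and there is 1 per condition.

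The only repeated comparison is that of VEGF against no VEGF at 4 matched times, which are different times and not replicates. It was tested with limma (lmFit and eBayes) with time as a block, over the 14446 genes above the floor on at least 4 of the 17 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. This fit leaves 3 residual degrees of freedom. Its residual holds array noise and the change of the VEGF difference with time, so its SE is not a replicate error. The change of the VEGF difference per doubling of time was tested in the same 8 arrays. Camera, limma's gene list test, was run with a preset correlation of 0.01 and with an estimated correlation, for the VEGF effect and, added after the data were examined, for its change with time. On simulated data with 200 changed genes among 14446, the VEGF fit recovered 53.3% of genes changed by 1 log2 unit, 86.7% of those changed by 2 and 83.8% of those changed by 3, with 6 false calls among 157. The simulated effects were the same at all 4 times, so these percentages do not apply to effects that change with time. They also depend on the 200 changed genes, since an adjusted p depends on how many genes have a low p. With fewer changed genes a single gene needs a lower p to pass. The test of change with time made 0 false calls among 14446 simulated genes. No such change was simulated, so its power was not checked.

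All other comparisons set 1 array against 1 array. They have no p-value and no replicate check, and no value in them carries an error. Genes with a 2-fold difference or more were counted. A gene list was described by the median log2 difference of its members above the floor on at least 1 of the arrays, and by the percentile of that median among 10000 random lists of the same size matched on mean expression. A list whose median lies outside the middle 95% of the random lists is said to stand apart, which describes those arrays only. On simulated lists with no shift, 1% were placed above that range and 0% below it, over 12516 genes.

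The 22 gene lists held 388 members, of which 374 were found: pluripotency, early mesoderm, endothelial markers, endothelial transcription factors other than the targets, targets, smooth muscle, pericyte, blood, Notch and arterial, immediate early and ERK feedback, cell cycle, extracellular matrix and mesenchyme, cardiac muscle, YAP and TAZ targets, BMP and TGF-beta response, interferon response, endoderm, neural, epithelial, hypoxia and glycolysis, p53 response and housekeeping. VEGF-induced genes were those at least 2-fold higher with VEGF at both 24 h and 48 h, and VEGF-repressed genes those at least 2-fold lower at both. The lists, comparisons, thresholds and rule for naming genes were fixed before the data were examined. The rule names the 4 targeted genes in every array. It names the 10 genes with the highest and the 10 with the lowest mean VEGF difference among those of the same sign at all 4 times, since none passed the threshold. For each pair of arrays it takes the 10 largest differences each way among genes above the floor on both arrays, for each list up to 4 members with the largest differences, the cell type markers Pecam1, Cdh5, Acta2, Tagln, Pou5f1 and Kdr, and the 10 VEGF-induced genes that fell most in si-Mix. From the lists of 10 for pairs of arrays, the text gives those most relevant to the comparison or with both signals above 133.5, the 60th percentile, and this narrowing was made after their values were seen.

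The single knockdowns share 1 control array, so their overlaps are given beside simulated unchanged arrays against that control, with the array spread taken from si-control*4 against si-control. Alternatives were quantile normalization, centring each array on its median, a floor at the 20th or 60th percentile, and the mean of all probe sets of a gene. For the limma tests, the filter on dim genes, the time block, the prior variance and each of the 4 times were also varied. The other control array, a covariate for the dim signal of each array, and VEGF-induced genes without the 4 targets were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.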

Results

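Gene expression was measured in ES cells, in sorted Flk mesoderm cells, in their progeny 6, 12, 24 and 48 h after replating with or without VEGF, and in cells under VEGF that received siRNA. With VEGF these cells form endothelial cells and without it smooth muscle cells, per the labels' protocols. The siRNA arrays comprised a control, single knockdowns of Gata2, Fli1, Sox7 and Sox18, a second control labelled si-control*4, and a mixture of the 4 siRNAs labelled si-Mix. Each of the 17 conditions had 1 array, so no value below carries a replicate error. Between 56.6% and 70.4% of probe sets lay above the floor in the 10 arrays of the time course and starting cells, and between 53.3% and 55.6% in the 7 siRNA arrays. The 3'/5' signal ratio lay between 1.15 and 1.36 for the actin controls and between 0.760 and 0.910 for the Gapdh controls.

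The first comparison asked how the sorted mesoderm differed from ES cells. In Flk mesoderm 1853 genes were at least 2-fold higher and 1669 at least 2-fold lower. All 18 early mesoderm genes were at least 2-fold higher, with a median log2 difference of 5.37, above all random lists. Mixl1 rose from a signal of 60.7 to 10920 (log2 difference 7.49) and Hand1 from 63.1 to 4844 (6.26). Kdr, which encodes the sorting marker Flk1, was at the floor in ES cells and at 3842 in the sorted cells, a log2 difference of at least 6.39. Of 18 pluripotency genes, 15 were at least 2-fold lower, with a median of -2.93. Zfp42 fell from 14131 to 102 and Pou5f1 from 12941 to 2476. The lists of smooth muscle (median 1.94), pericyte (2.55), Notch and arterial (2.12), BMP and TGF-beta response (1.78), hypoxia and glycolysis (1.72), YAP and TAZ targets (1.16), immediate early and ERK feedback (0.96) and extracellular matrix and mesenchyme (0.95) also stood apart as higher. The endoderm list stood apart as higher too (0.75). The cell cycle (-0.42), p53 response (-0.35), epithelial (-0.63) and neural (-0.66) lists stood apart as lower. Endothelial markers did not stand apart, with a median of -0.28 at percentile 6.8. Among them, Pecam1 was at 654.3 in ES cells and at the floor in Flk mesoderm.

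The next comparison asked what the sorted cells became after 48 h with and without VEGF. Against Flk mesoderm, 1374 genes were at least 2-fold higher and 1081 lower with VEGF, and 2113 were higher and 1454 lower without it. Endothelial markers stood apart with VEGF and not without it, with a median of 3.18 and 29 of 32 measured members at least 2-fold higher. Without VEGF their median was 0.30, at percentile 94.9, although Pecam1 rose there from the floor to 362. The other endothelial transcription factors had medians of 1.64 with and 0.26 without VEGF. Blood genes also stood apart with VEGF (0.80) and not without it (0.17). Their median with against without VEGF at 48 h was nonetheless -0.14, within the random lists. For p53 response genes the medians were close, at 0.37 with VEGF, which stood apart, and 0.32 without it, at percentile 96.9. Their median with against without VEGF at 48 h was nonetheless 0.24, which stood apart. Endoderm genes stood apart as lower without VEGF (-0.79) and not with it (0.26). The Notch and arterial list had medians of opposite sign, 0.53 with and -1.28 without VEGF. With VEGF its members split, with 5 at least 2-fold higher and 6 at least 2-fold lower. Several other lists changed in the same direction in both cultures. Some of them still stood apart with against without VEGF at 48 h, such as matrix and mesenchyme genes (-0.61). Smooth muscle genes had medians of 2.17 with and 2.36 without VEGF, and matrix and mesenchyme genes 2.60 and 2.82. Acta2 rose from 1992 in Flk mesoderm to 39755 with VEGF and 53401 without it, and Tagln from 1995 to 18156 and 27027. Early mesoderm genes had medians of -2.58 and -2.56, pluripotency genes -1.54 and -1.44, and hypoxia and glycolysis genes -1.37 and -1.45. Immediate early genes had medians of -0.95 with and -1.57 without VEGF, cardiac muscle genes 1.07 and 0.98, YAP and TAZ targets 1.17 and 1.49, and cell cycle genes -0.31 and -0.49.

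**Figure D1:**
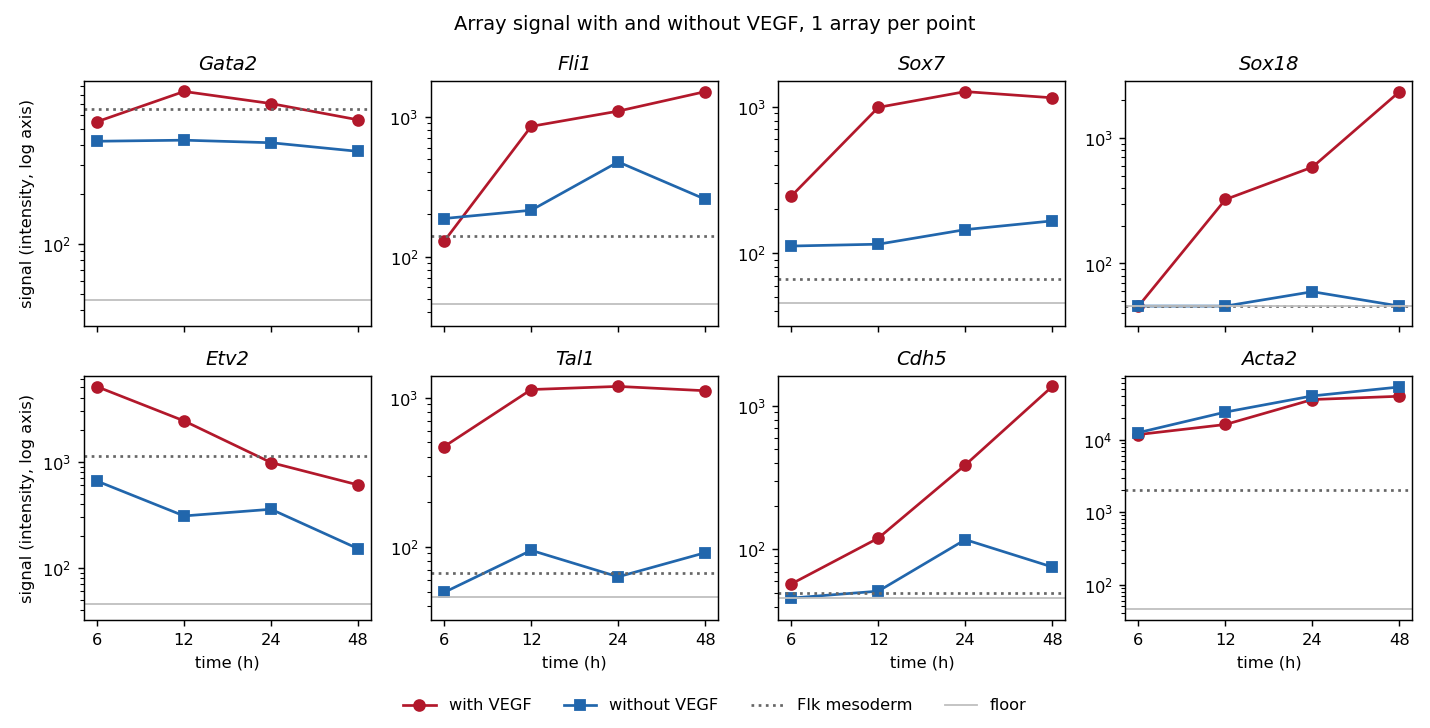
Signal (intensity, log axis) of 8 genes at 4 times with VEGF (circles) and without (squares), 1 array per point; dotted lines give Flk mesoderm and grey lines the floor. Etv2 is highest at 6 h with VEGF (5078), while Sox18 and Cdh5 are highest at 48 h (2329 and 1362).

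The series was designed to find genes activated by VEGF, and each time had 1 pair of arrays with and without it. Among the 4 genes later targeted by siRNA, Sox18 was at the floor at 6 h in both cultures. With VEGF it reached 323 at 12 h, 585 at 24 h and 2329 at 48 h, against 59.6 at 24 h and floor values at the other times without VEGF. Sox7 was at 246, 991, 1270 and 1152 with VEGF at 6, 12, 24 and 48 h, and at 112, 115, 145 and 166 without. Fli1 was lower with VEGF at 6 h (129 against 187) and higher at the later times (855 against 214, 1098 against 476 and 1515 against 257). Gata2 was at 550 against 419 at 6 h, 838 against 425 at 12 h, 708 against 410 at 24 h and 564 against 364 at 48 h. A second probe set of Gata2 had larger log2 differences at 12 h (2.36 against 0.98) and 48 h (1.25 against 0.63).

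The leading genes changed over time. At 6 h the largest VEGF differences among genes above the floor on both arrays were those of Tal1 (469 against 49.4, log2 difference 3.25) and Etv2 (5078 against 656, 2.95), followed by Mmrn2 (2.17) and Rhoj (2.17). At 12 h they were Lmo2 (1559 against 54.9, 4.83), Tal1 (3.58), Rhoj (3.33), Sox7 (3.11), Etv2 (2.97), Hip1r (2.80) and Hhex (2.48). Etv2 was at its highest at 6 h with VEGF and fell to 604 at 48 h, when it was at 152 without VEGF. At 24 h Tal1 (4.24), Ramp2 (3.99), Hhex (3.34), Sox18 (3.29), Sox7 (3.13) and Cd34 (3.00) led among genes above the floor on both arrays, while Lmo2 was at 1422 against the floor (at least 4.96). At 48 h the leading genes were Hapln1 (2385 against 77.4, 4.95), Cdh5 (1362 against 75.4, 4.17), Ramp2 (4.05), Prkar2b (4.04), Mmrn2 (3.88), Clec1b (3.86), Sox17 (3.76), Cd93 (3.69), Myct1 (3.68) and Tal1 (3.61). Cd34, Plvap and Icam2 were at the floor without VEGF at 48 h and at least 6.00, 4.59 and 4.24 log2 units higher with it. Pecam1 was no higher with VEGF at 12 h (106 against 115) or 24 h (190 against 228) and higher at 48 h (790 against 362). Kdr was at 1071 with VEGF and 1121 without at 6 h, and at 1243 and 246 at 48 h. None of the 10 genes with the largest fall at any time had a signal above the 60th percentile on both arrays.

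The counts of genes at least 2-fold higher and lower alternated with time. They were 1007 and 279 at 6 h (78.3% higher), 234 and 684 at 12 h (25.5%), 1097 and 549 at 24 h (66.6%), and 519 and 949 at 48 h (35.4%). After quantile normalization they were 354 and 367 (49.1%), 275 and 297 (48.1%), 650 and 598 (52.1%), and 518 and 480 (51.9%). That step gives all arrays the same distribution, which can draw such counts together. It does not fix them, since in si-Sox7 against si-control 38.4% were then higher. With the floor at the 60th percentile 56.1%, 58.6%, 60.1% and 79.4% were higher in the VEGF comparisons. Centring each array on its median kept their alternation (81.4%, 24.2%, 68.4% and 28.1%). The direction of these counts at 12 h and 48 h thus depends on the floor. Over genes above the floor on both arrays, the same centring moved the median difference at 48 h from -0.01 to -0.12. It moved that of 48 h without VEGF against Flk mesoderm from -0.05 to 0.05. The list percentiles below are relative to genes of like expression.

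Endothelial lists stood above all random lists at each time. The median difference of endothelial markers was 0.46 at 6 h, 0.36 at 12 h, 1.56 at 24 h and 2.87 at 48 h, when 28 of 33 measured members were at least 2-fold higher. The other endothelial transcription factors had medians of 0.53, 0.58, 0.64 and 1.28. Immediate early and ERK feedback genes had medians of 0.44, 0.42, 0.31 and 0.35; at 6 h Dusp6 was at 4172 against 1918 and Egr1 at 2236 against 1160. Notch and arterial genes stood apart only at 48 h, with a median of 0.60, when Hey1 was at 704 against 124 and Gja4 was at 1002 against the floor. Smooth muscle genes had medians of 0.06 at 6 h, -0.25 at 12 h, -0.11 at 24 h and -0.24 at 48 h, and Acta2 was at 39755 with and 53401 without VEGF at 48 h. The smooth muscle median at 48 h lay within the random lists after quantile normalization (median -0.12). Matrix and mesenchyme genes had medians of 0.17, -0.25, -0.15 and -0.61; Col1a1 was at 1525 with and 4059 without VEGF at 48 h. Cell cycle genes stood apart at 24 h (median 0.13) and 48 h (0.20). Lists of other cell types and responses moved as well. Blood genes stood apart as higher at 24 h (0.71), endoderm genes at 24 h (0.69) and 48 h (0.27, but -0.06 with the floor at the 60th percentile), and p53 response genes at 48 h (0.24). Early mesoderm genes stood apart as lower at 12 h (-0.37) and 48 h (-0.39), pericyte genes at 48 h (-0.61) and housekeeping genes at 48 h (-0.29). BMP and TGF-beta response genes were higher at 12 h (0.23) and lower at 48 h (-0.25), and interferon response genes lower at 12 h (-0.65) and higher at 48 h (0.32). After quantile normalization both lay within the random lists at 48 h (-0.13 and 0.32), as did p53 response (0.14) and pericyte genes (-0.39) at 48 h and endoderm genes at 24 h (0.37). YAP and TAZ targets were higher at 6 h (0.12) and lower at 24 h (-0.19) and 48 h (-0.25).

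**Figure D2:**
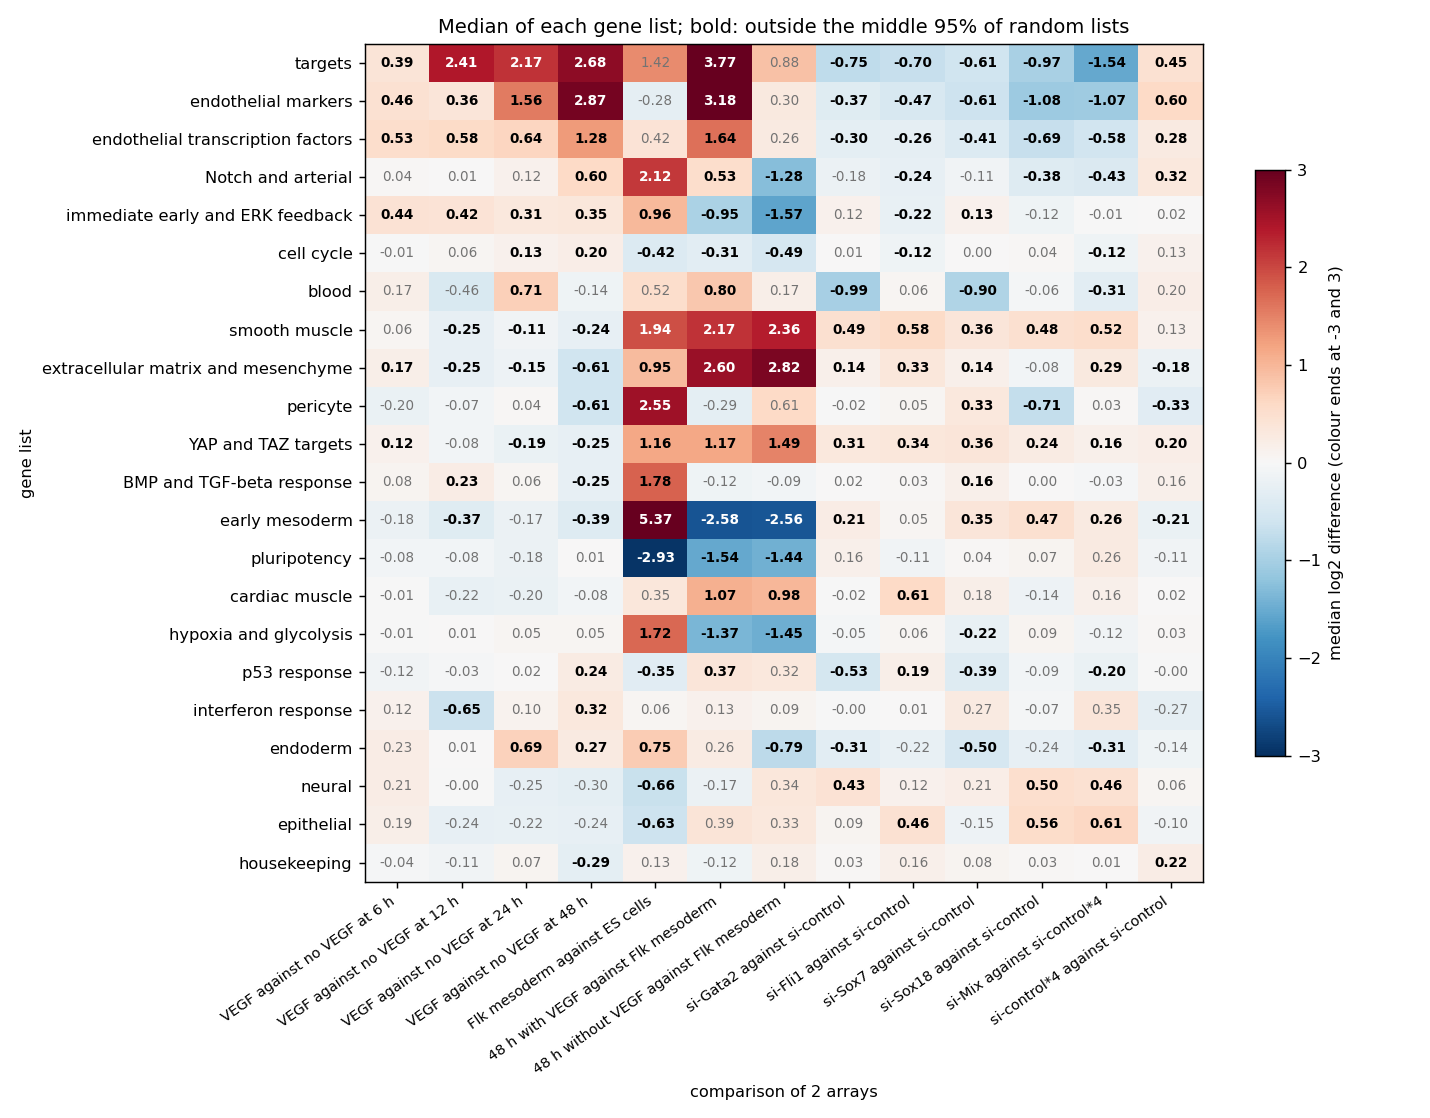
Median log2 difference of 22 gene lists (vertical axis) in 13 comparisons of 2 arrays (horizontal axis), as colour and number; bold numbers lie outside the middle 95% of random lists. Endothelial markers are at 2.87 at 48 h with against without VEGF and at -1.07 in si-Mix, while smooth muscle genes are between 0.36 and 0.58 in the 5 knockdown comparisons.

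Across the 4 matched times, limma found 0 of 14446 genes with a VEGF effect at an adjusted p under 0.05; at an unadjusted p under 0.05 there were 430 higher and 533 lower. It found 0 genes whose VEGF effect changed with time, with 466 rising and 534 falling at an unadjusted p under 0.05. Each SE below holds the change of the difference with time as well as array noise. The 0 calls thus do not show a lack of a VEGF effect. Tal1 came closest, with a mean log2 difference of 3.67 (SE 0.185, adjusted p 0.0926) and higher values at 4 of 4 times. The other genes with the highest mean difference and the same sign at 4 of 4 times, none past the threshold, were Ramp2 (2.88, SE 0.725), Rhoj (2.85, SE 0.217), Sox7 (2.54, SE 0.380), Etv2 (2.34, SE 0.304), Hhex (2.12, SE 0.438), Esam (2.00, SE 0.445), Cdh5 (1.86, SE 0.646), Prkar2b (1.85, SE 0.651) and Sox17 (1.84, SE 0.524), with adjusted p between 0.349 for Rhoj and 0.731 for Cdh5 and Prkar2b. For Cdh5, a dim second probe set was lower with VEGF at 12 h (-1.18) and higher at 6 h (0.38), 24 h (1.65) and 48 h (2.98). The 10 with the lowest means ran from Tango2 (-1.20, SE 0.174), Svep1 (-1.06, SE 0.156) and Fendrr (-1.06, SE 0.183) through Tub, Cxcl12, Plaat1, 4930429D17Rik, Nav2 and Hand2 to Pdlim4 (-0.90, SE 0.116), with adjusted p between 0.603 and 0.731. Of 10100 genes above the floor on all 8 arrays, 7.74% were higher and 9.36% lower with VEGF at all 4 times, against 6.25% each by chance. Among these 10100, Tal1, Rhoj, Sox7, Etv2 and Esam were the 5 genes at least 2-fold higher at all 4 times, and 0 were at least 2-fold lower at all 4.

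In camera with the preset correlation, 7 of 22 lists passed an adjusted p under 0.05 for the mean VEGF effect. Endothelial markers (median 1.19, adjusted p 8.5e-11), the other endothelial transcription factors (0.69, 9.8e-09), immediate early and ERK feedback (0.38, 4.4e-07), targets (1.92, 7.6e-06) and cell cycle (0.09, 0.0131) rose. Early mesoderm (-0.24, 0.0239) and smooth muscle (-0.14, 0.0374) fell. With the estimated correlation none of the 7 held, and the lowest adjusted p was 0.210, for immediate early and ERK feedback. The lists that did not pass, with their preset adjusted p, were matrix and mesenchyme (0.0638), Notch and arterial (0.0909), blood (0.110), pericyte (0.110), BMP and TGF-beta response (0.249), YAP and TAZ targets (0.249), endoderm (0.398), housekeeping (0.398), p53 response (0.398), pluripotency (0.456), epithelial (0.456), cardiac muscle (0.701), hypoxia and glycolysis (0.933), neural (0.949) and interferon response (0.949). For cardiac muscle and neural genes the test's direction was down while their mean differences were 0.08 and 0.02. Adjusted over the list alone, limma called 8 transcription factors, 5 immediate early genes, 3 targets and 1 early mesoderm gene as higher, and 6 early mesoderm and 2 pericyte genes as lower; over all genes tested it called 0 of them.

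The siRNA arrays asked which genes depend on each of the 4 transcription factors. Each target was lower in its own knockdown than in si-control. Gata2 fell from 727 to 351 (log2 difference -1.05), Fli1 from 2217 to 716 (-1.63), Sox7 from 1031 to 590 (-0.80) and Sox18 from 1158 to 292 (-1.99). In si-Mix against si-control*4, Gata2 was at 544 against 865 (-0.67), Fli1 at 591 against 1735 (-1.55), Sox7 at 563 against 1624 (-1.53) and Sox18 at 584 against 1854 (-1.67). The controls themselves differed: in si-control*4 against si-control, Sox18 was higher by 0.68, Sox7 by 0.66 and Gata2 by 0.25, and Fli1 was at -0.35. A second probe set of Fli1 was at 1.22 in that comparison of controls, opposite in sign, and at -1.23 in si-Fli1 and -1.95 in si-Mix. A second probe set of Gata2 was at -1.19 in si-Gata2 and at -0.18 in si-Mix. Several targets were also lower in other knockdowns. In si-Sox18, Fli1 was at -1.07, Gata2 at -0.87 and Sox7 at -0.71, and Sox18 was at -0.94 in si-Gata2, -0.84 in si-Fli1 and -0.60 in si-Sox7. Gata2 was at -0.03 in si-Fli1, where its second probe set was at -0.33. The second probe set of Fli1 was at -0.10 in si-Gata2, -0.09 in si-Sox7 and -0.44 in si-Sox18. For Sox7, the fall in its own knockdown was close to its fall in si-Sox18 and to the difference between the controls.

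**Figure D3:**
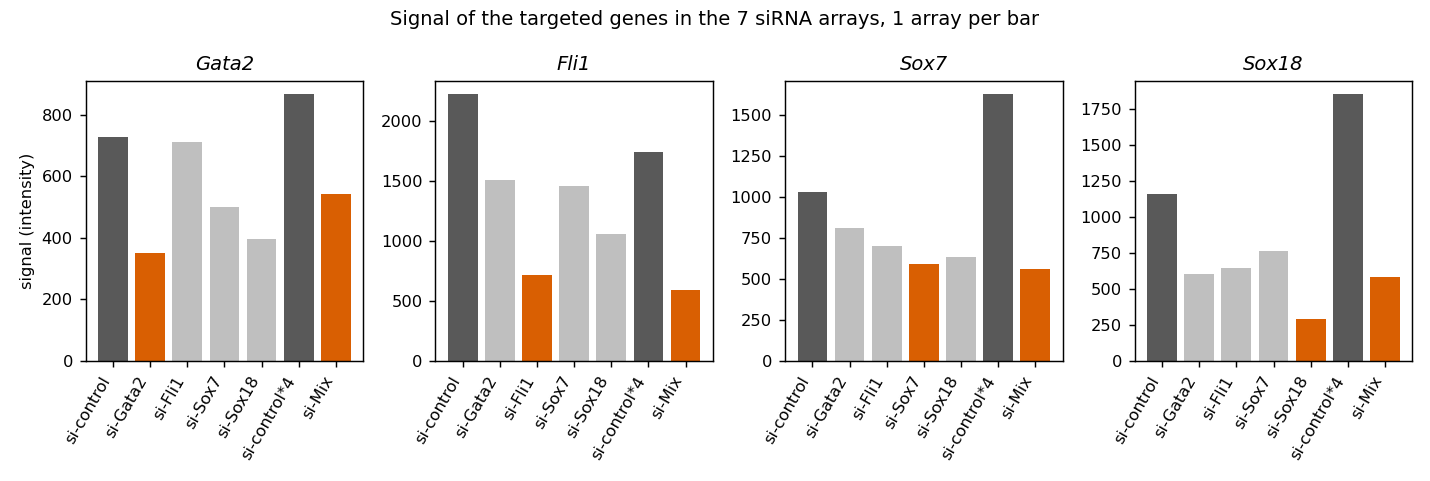
Signal (intensity, linear axis from 0) of the 4 targeted genes in the 7 siRNA arrays, 1 array per bar; orange bars are arrays that received the gene's siRNA and dark bars the controls. Sox18 is at 292 in si-Sox18 against 1158 in si-control, and Sox7 at 590 in si-Sox7 against 1031.

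Against si-control, 146 genes were at least 2-fold higher and 192 lower in si-Gata2, 165 and 168 in si-Fli1, 133 and 253 in si-Sox7, and 205 and 318 in si-Sox18. Against si-control*4, 230 were higher and 276 lower in si-Mix. The comparison of the 2 controls gave 97 higher and 152 lower, which is the size of difference seen with no target. In si-Sox18 the share of changed genes that were higher was 39.2% (51.2% after quantile normalization, with 255 higher and 243 lower). Cdkn2b was among the 10 genes that rose most in si-Gata2 (1.68), si-Fli1 (2.05), si-Sox18 (2.19) and si-Mix (2.54), where it went from 454 to 2640. Igfbp5 rose by 1.49 in si-Gata2, 1.91 in si-Sox18 and 2.00 in si-Mix. In si-Fli1, Ldb3 (3.20) and Actg2 (2.46) rose most and Malat1 (-2.39) fell most. In si-Sox7, Col8a1 (1.88) rose and Aldh1a1 (-2.26) fell. In si-Sox18, Slc6a15 (2.23) and Sema3c (2.01) rose and Clec1b (-2.09), Myrf (-2.01) and Emilin1 (-1.92) fell. In si-Mix, Prss23 (2.10) and Itpripl2 (1.97) rose and Oit3 (-2.16) and Zfp777 (-1.92) fell. Embryonic globin Hbb-bh1 was lower in si-Gata2 (64.0 against 634, -3.31), si-Sox7 (-2.73), si-Sox18 (-1.93) and si-Mix (-1.70), and higher in si-Fli1 (1.67).

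Genes that VEGF had induced in the time course were lower in each knockdown comparison. Of 116 VEGF-induced genes, 14 are in the list of endothelial markers, 6 in that of the other endothelial transcription factors, 4 in that of Notch and arterial genes and 3 are targets. Their median log2 difference was -0.44 in si-Gata2, -0.34 in si-Fli1, -0.60 in si-Sox7, -0.77 in si-Sox18 and -0.80 in si-Mix, each below all random lists. At least 2-fold lower were 10 of 114 measured genes in si-Gata2, 7 of 113 in si-Fli1, 22 of 115 in si-Sox7, 40 of 113 in si-Sox18 and 35 of 114 in si-Mix. The same genes were higher in si-control*4 than in si-control, with a median of 0.30, above all random lists. A place beyond all random lists thus does not by itself mark an effect of a target. Against the other control the medians were -0.79, -0.68, -0.89 and -1.18 in the single knockdowns and -0.43 in si-Mix. All 5 knockdown arrays thus lay below both control arrays, but the order of si-Mix among them depends on the control. In si-Mix the VEGF-induced genes that fell most were BC028528 (-1.72), Myb (-1.67 or lower, at the floor in si-Mix), Sox18 (-1.67), Gja4 (-1.66), Adgrl4 (-1.61), Bcl6b (-1.56), Fli1 (-1.55), Sox7 (-1.53), Gad2 (-1.52) and Lmo2 (-1.44). Of the 66 VEGF-repressed genes, 32 were also called after quantile normalization and 7 with the floor at the 60th percentile, so this set is unstable. The 66 genes stood above the random lists in si-Gata2 (0.14) and si-Mix (0.22). Both lay within the random lists against the other control (0.14 at percentile 94.2 and 0.03 at percentile 63.1), while si-Sox7 (0.25) and si-Sox18 (0.20) stood apart, so this too depends on the control.

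Endothelial markers had medians of -0.37 in si-Gata2, -0.47 in si-Fli1, -0.61 in si-Sox7, -1.08 in si-Sox18 and -1.07 in si-Mix. In si-control*4 against si-control their median was 0.60, above all random lists. The falls in si-Gata2 and si-Fli1 were thus smaller than the difference between the controls, and that in si-Sox7 was about its size. Cdh5 was at -1.59 in si-Sox7, -1.55 in si-Sox18, -1.31 in si-Mix, -0.85 in si-Fli1 and -0.44 in si-Gata2. A dim second probe set of Cdh5, with a mean signal of 78.7, lay between -0.64 in si-Mix and -0.06 in si-Fli1. The other endothelial transcription factors had medians of -0.30, -0.26, -0.41, -0.69 and -0.58, and of 0.28 between the controls, about the size of the falls in si-Gata2 and si-Fli1. Their medians against the other control were -0.68, -0.56, -0.56 and -0.93 in the single knockdowns and -0.46 in si-Mix. Notch and arterial genes stood apart in si-Fli1 (-0.24), si-Sox18 (-0.38) and si-Mix (-0.43), and between the controls (0.32). All 5 knockdowns stood apart against the other control, with medians of -0.29 in si-Gata2, -0.59 in si-Fli1, -0.33 in si-Sox7, -0.48 in si-Sox18 and -0.25 in si-Mix, so which knockdowns stand apart depends on the control.

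Smooth muscle genes stood above all random lists in each knockdown comparison, with medians of 0.49 in si-Gata2, 0.58 in si-Fli1, 0.36 in si-Sox7, 0.48 in si-Sox18 and 0.52 in si-Mix, and 0.13 between the controls. They also stood apart against the other control, with medians of 0.27, 0.44, 0.19 and 0.36 in the single knockdowns and 0.69 in si-Mix. Lists of other lineages stood apart as higher too. Epithelial genes did so in si-Fli1 (0.46), si-Sox18 (0.56) and si-Mix (0.61), and neural genes in si-Gata2 (0.43), si-Sox18 (0.50) and si-Mix (0.46). These also stood apart against the other control, except neural genes in si-Sox18 (0.10), and epithelial genes in si-Gata2 then stood apart as well (0.28). Endoderm genes stood apart as lower in si-Gata2 (-0.31), si-Sox7 (-0.50) and si-Mix (-0.31), and with the other control in si-Gata2 (-0.33) and si-Sox7 (-0.52) but not in si-Mix (-0.24). Cell cycle genes stood apart as lower in si-Fli1 (-0.12, and -0.25 with the other control) and si-Mix (-0.12, and -0.05 within the random lists with the other control), and with the other control also in si-Sox18 (-0.12). Hypoxia and glycolysis genes stood apart as lower in si-Sox7 (-0.22), though not with the other control (-0.21). YAP and TAZ targets were higher in the 5 knockdown comparisons (medians from 0.16 to 0.36) and also in si-control*4 against si-control (0.20); against the other control array they lay within the random lists in si-Fli1 (0.09) and si-Sox18 (0.00). Matrix and mesenchyme genes had medians of 0.14 in si-Gata2, 0.33 in si-Fli1, 0.14 in si-Sox7, -0.08 in si-Sox18 and 0.29 in si-Mix. Between the controls their median was -0.18, which stood apart. Against the other control the medians were 0.20, 0.33, 0.29 and 0.06 in the single knockdowns and 0.28 in si-Mix. Early mesoderm genes were higher in si-Gata2 (0.21), si-Sox7 (0.35), si-Sox18 (0.47) and si-Mix (0.26), and lower in si-control*4 than in si-control (-0.21). With the other control early mesoderm genes stood apart in all 5, with medians of 0.45 in si-Gata2, 0.31 in si-Fli1, 0.41 in si-Sox7, 0.59 in si-Sox18 and 0.22 in si-Mix. Blood genes had medians of -0.99 in si-Gata2 and -0.90 in si-Sox7, below all random lists, and -0.31 in si-Mix, with Csf1r at -1.54 in si-Gata2 and -2.24 in si-Sox7. Blood medians against the other control were -0.48 in si-Gata2, -0.62 in si-Sox7 and -0.42 in si-Mix, and si-Sox18 stood apart as well (-0.42, against -0.06 with si-control). Cardiac muscle genes stood apart in si-Fli1 only (0.61), with Actc1 at 12642 against 5824, Tnnc1 at 3234 against 1635, Myl4 at 908 against 464 and Tnni1 at 1104 against 590. Pericyte genes were lower in si-Sox18 (-0.71) and higher in si-Sox7 (0.33), over 5 measured genes each, and differed by -0.33 between the controls. Pericyte genes against the other control stood apart in si-Sox18 (-0.50, over 4 genes) and si-Fli1 (0.39) and lay within the random lists in si-Sox7 (0.33).

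**Figure D4:**
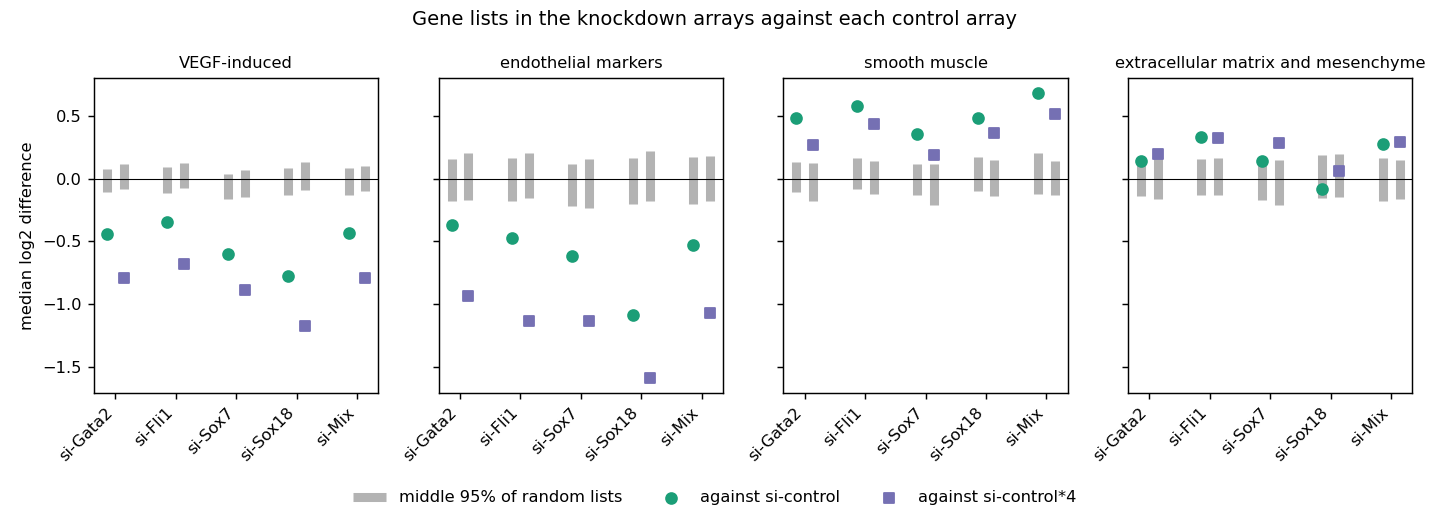
Median log2 difference (vertical axis) of 4 gene lists in the 5 knockdown arrays (horizontal axis) against each control array; grey bars give the middle 95% of random lists. VEGF-induced genes and endothelial markers lie below the bars and smooth muscle genes above them with either control, for example -0.34 and -0.68 for VEGF-induced genes in si-Fli1.

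The knockdowns were compared with each other across 10234 genes, which are not independent replicates. Pairs of single knockdowns share si-control, and simulated unchanged arrays against that control gave a correlation of 0.499. The observed correlations were below that in 4 of the 6 pairs (0.462, 0.460, 0.451 and 0.475) and above it in si-Gata2 with si-Sox7 (0.601) and with si-Sox18 (0.588). The 0.499 follows from giving all simulated arrays the same spread. Effects particular to 1 knockdown lower the correlation, so a value below 0.499 does not argue against shared effects. The covariance exceeded the simulated 0.0527 by 0.0114 to 0.0424. That simulation takes the difference between the controls as noise, though endothelial markers differed between them by 0.60. Overlaps were above those of independent lists: for si-Sox7 and si-Sox18, 62 genes were lower in both against 4.47 expected from independent lists and 4.50 from unchanged arrays sharing the control. The simulated overlap leaves out real effects and that of independent lists the shared control, so part of the excess may come from the shared control. si-Sox18 and si-Mix share no array, and 73 genes were lower in both against 4.47 expected from independent lists. Their correlation was 0.442, and 0.335 with the controls exchanged. The correlation with si-Mix was 0.418 for si-Gata2, 0.296 for si-Fli1 and 0.436 for si-Sox7, and 0.282, 0.222 and 0.261 with the controls exchanged.

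The mixture was set against the sum of the single knockdowns over 94 VEGF-induced genes without the 4 targets. The median of the summed log2 differences was -2.37, against -0.85 in si-Mix with si-control*4 and -0.49 in si-Mix with si-control, and the median of the strongest single knockdown was -0.90. In 89 of the 94 genes the difference in si-Mix against si-control*4 was smaller in absolute size than the sum, whatever the signs. The sum counts the si-control array 4 times, and VEGF-induced genes without the 4 targets were higher on si-control*4 by a median of 0.29, so the size of the sum depends on the control.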

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

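All tests in this part were chosen after the results were seen. A signal outside the main measurement set the siRNA arrays apart. The poly-A spike controls had a geometric mean of at least 395.7 on each of the 7 siRNA arrays and of at most 17.3 on the other 10. The 18S ribosomal RNA probe sets had a geometric mean of at least 5693 on the siRNA arrays and of at most 66.0 on the others. The labels name no batch. These values separate the 2 sets of arrays completely, so a difference between a siRNA array and a time course array and a difference between the sets cannot be told apart, and none is reported.

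Some lists moved in opposite directions at different times of the VEGF comparison or in different knockdowns, each standing apart from the random lists in both directions, as deposited and after quantile normalization. The differences between knockdowns were not tested, since each value rests on 2 arrays. Matrix and mesenchyme genes were higher with VEGF at 6 h (median 0.17) and lower at 48 h (-0.61). YAP and TAZ targets were higher at 6 h (0.12) and lower at 48 h (-0.25). In camera on the change of the VEGF difference per doubling of time, with the preset correlation, both fell (median change -0.22, adjusted p 3.1e-05, and -0.13, adjusted p 0.0427). With the estimated correlation neither passed (adjusted p 0.453 each). At 6 h several of the matrix genes behind the shift were near the floor: Col3a1 was at 119, Postn at 93.8 and Prrx1 at 91.6 with VEGF, and each was at the floor without it. Among the knockdowns, p53 response genes were lower in si-Gata2 (-0.53, with Perp at 884 against 1912) and higher in si-Fli1 (0.19, with Cdkn1a at 9882 against 5998). Against the other control array these medians were -0.47 and 0.19. They were also lower in si-Sox7 (-0.39, below all random lists) and si-Mix (-0.20). Against the other control array si-Sox7 was at -0.42, below all random lists, and si-Mix at -0.18, within them at percentile 2.6. Immediate early and ERK feedback genes were higher in si-Sox7 (0.13) and lower in si-Fli1 (-0.22). Against the other control array their medians were 0.06 and -0.10, both within the random lists, so this pair rests on the si-control array.

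The excess of higher over lower genes alternated with time in the VEGF comparisons, at 78.3%, 25.5%, 66.6% and 35.4% higher. The arrays with the higher signal of dim probe sets in their pair were VEGF at 6 h (40th percentile 74.1 against 50.6) and 24 h (70.0 against 57.8) and no VEGF at 12 h (61.6 against 45.8) and 48 h (66.8 against 47.1), which is the same alternation. With the floor raised to the 60th percentile, which removes these probe sets, the share that was higher was 58.6% at 12 h and 79.4% at 48 h, so the excess of lower genes was gone at both. The alternation is consistent with an unequal signal of dim probe sets between arrays. A response in which VEGF lowers more genes than it raises at 48 h is argued against by the 79.4%, for genes above that floor. A change of the number of weakly expressed genes stays open, as it was not tested.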

How the results depend on the processing

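The other control array, the dim signal covariate, VEGF-induced genes without the 4 targets, and the test of change with time under median centring, other floors and the mean of probe sets were tried after the data were examined. The cause of the changes below was not tested except where stated.

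The direction of the VEGF-induced genes held in all 5 knockdown comparisons under each alternative, always below all random lists. These genes also lay beyond all random lists between the controls, on the higher side. Over the 5 alternatives in scaling, floor and probe sets their medians ranged from -0.49 to -0.30 in si-Gata2, -0.34 to -0.19 in si-Fli1, -0.64 to -0.32 in si-Sox7, -0.96 to -0.47 in si-Sox18 and -0.90 to -0.38 in si-Mix. The genes called VEGF-induced numbered between 50 (floor at the 60th percentile) and 408 (20th), against 116. After quantile normalization 91 of the 116 were shared. Those called VEGF-repressed numbered between 7 (60th) and 476 (20th), against 66, and 32 of the 66 were shared after quantile normalization.

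For the VEGF effect over the 4 times, limma called 0 genes under every alternative, each time left out included, except 3 with a trend in the prior variance (Tal1, Rhoj and Cyp26a1) and 1 with the mean of all probe sets (Tal1). The adjusted p of Tal1 ranged from 0.00446 to 0.905 over the alternatives. Without the time block there were 0 calls, with 205 genes higher and 190 lower at an unadjusted p under 0.05. The test of change with time called 0 genes under the alternatives run for it, which were scaling, floors, mean of probe sets, no filter and prior variance with a trend. Of the lists, 7 passed with the preset correlation and 0 with the estimated correlation, both for the VEGF effect and for its change with time; the second test was added after the data were examined.

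Counts of 2-fold genes depend on the floor by construction, since a lower floor admits larger ratios of dim signals. In the order higher then lower, with the floor at the 20th percentile (signal 13.5) they were 2457 and 1178 at 6 h, 1207 and 2256 at 12 h, 2408 and 1733 at 24 h and 1491 and 2501 at 48 h for VEGF; 3054 and 2511 for Flk mesoderm; 2428 and 2111 for 48 h with VEGF and 3664 and 2390 without; 1052 and 1060 in si-Gata2, 1241 and 997 in si-Fli1, 1049 and 1119 in si-Sox7, 1069 and 1244 in si-Sox18, 1307 and 1335 in si-Mix and 1109 and 1057 between the controls. With the floor at the 60th percentile (133.5) they were 64 and 50 at 6 h, 58 and 41 at 12 h, 131 and 87 at 24 h and 227 and 59 at 48 h for VEGF; 49 and 72 in si-Gata2, 55 and 55 in si-Fli1, 41 and 113 in si-Sox7, 88 and 159 in si-Sox18, 65 and 125 in si-Mix and 14 and 48 between the controls. Lower genes for 48 h with VEGF against Flk mesoderm then numbered 716 and higher genes for 48 h without it 1019; the other counts from the starting cells stayed within 1.5 times. At the 20th percentile floor the 2 controls differ in about as many genes as a knockdown and its control, so single dim genes are not resolved.

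After quantile normalization the counts that moved were 354 higher at 6 h, 297 lower at 12 h, 650 higher at 24 h and 480 lower at 48 h, all for VEGF. With the mean of all probe sets they were 646 and 180 at 6 h, 135 and 392 at 12 h, 320 lower at 24 h and 608 lower at 48 h for VEGF; 91 and 116 in si-Gata2, 90 lower in si-Fli1, 82 and 152 in si-Sox7, 117 and 182 in si-Sox18, 144 and 182 in si-Mix and 52 and 64 between the controls. With the other control array 234 genes were higher in si-Gata2 and 236 in si-Sox7. Median centring moved none of these counts by more than 1.5 times.

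Of 293 list medians, 266 kept their place inside or outside the random lists, with the same sign where outside, after quantile normalization, 285 after centring, 268 and 255 (of 292) with the lower and higher floor, 251 with the mean of probe sets, and 89 of 115 with the other control. Among medians outside the random lists, the sign reversed for endoderm at 48 h with VEGF (-0.063, floor at the 60th percentile), BMP and TGF-beta response in si-Sox7 (-0.033, other control), and pericyte between the controls (0.11, mean of probe sets). Medians inside the random lists also changed sign, for example BMP and TGF-beta response in si-Gata2, which was then outside them (-0.20, other control). Among named genes with a difference of at least 2-fold only Lats2 reversed, between the controls (0.031, mean of probe sets).

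The signal over background limits dim genes: between 53.3% and 70.4% of probe sets lay above the floor, and a difference against the floor is only a bound.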

Other observations

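All tests in this part were chosen after the results were seen. The limma results were set against other splits of the 8 time course arrays. Of 35 splits into 4 and 4, 32 could be fitted with the time block. At an unadjusted p under 0.05 the real split gave 963 genes, 11 of the 32, the real one included, gave as many, and the highest of the others gave 1143. For the change with time it gave 1000, with 15 of 32 as large and a highest other of 1498. For lists past the threshold in camera it gave 7, with 6 of 32 as large and a highest other of 11. For lists past the threshold in camera for the change with time it gave 7 of the 22, with 7 of 32 as large and a highest other of 9. Chance is therefore not excluded for any of these 4 counts. Adjusted calls of genes were 0 in all 32. The real split parts the 4 time-matched pairs, as only 8 splits do, and 3, 3, 2 and 3 of these 8 gave results as large; 8 splits are too few for a share under 0.05, and the other 24 part 2 pairs and form 12 distinct fits, each counted 2 times. Over the 20 distinct fits 7, 9, 4 and 5 were as large. The split with 1143 genes joins VEGF at 6 and 24 h with no VEGF at 12 and 48 h, the arrays with the highest 40th percentile signal. With that signal as a covariate, limma called 0 genes, with 567 higher and 619 lower at an unadjusted p under 0.05.

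Endothelial markers were lower in all 5 knockdown comparisons. Against the other control the 4 single knockdowns were also lower, with -0.93 (si-Gata2) as the highest of the 4 medians, below all random lists. These markers were 0.60 higher on that control than on si-control, so a lower place there largely follows from being below si-control. The other control thus cannot decide whether a high endothelial signal on the si-control array was the whole cause. In si-Mix the markers were also lower against si-control, with a median of -0.53. That is smaller than the 0.60 between the controls. It thus cannot decide whether a high signal on the si-control*4 array was the whole cause of the fall in si-Mix. The size of each fall still depends on the control, since the 2 controls differ by 0.60. A smaller share of endothelial cells in the knockdown cultures could lower these markers and raise those of other cells alike. If so, smooth muscle, matrix and mesenchyme, blood and pericyte genes would rise alike. Differences of medians were taken between smooth muscle and each of the other 3 lists, with 99.7% bootstrap intervals over genes, which allow for 15 comparisons. The test was revised more than once: it began with matrix and mesenchyme, 1 control and 95% intervals, which set si-Gata2 and si-Sox18 apart. The second control, and then blood and pericyte, whose medians had been seen, came later, so the intervals do not allow for every choice made. Smooth muscle minus blood was 1.48 (0.12 to 2.33) in si-Gata2 and 1.26 (0.32 to 2.87) in si-Sox7, and 0.75 (0.31 to 2.26) and 0.81 (0.14 to 1.83) against the other control, beyond the -0.06 between the controls. In si-Gata2 and si-Sox7 smooth muscle and blood genes thus did not move alike. This does not decide whether a smaller share of endothelial cells was the whole cause there. Blood genes stood apart as higher with VEGF at 24 h (0.71), though not at 48 h (-0.14), so a loss of endothelial cells could lower them too. The intervals hold the spread between genes on single arrays, not that between cultures. Most of these blood genes are dim, and Runx1 was higher in both. A fall of endothelial and blood cells together stays open.

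In the other 3 knockdowns no interval excludes 0 with both controls, so a smaller share and a lower expression per cell cannot be told apart there either. In si-Fli1, smooth muscle minus pericyte was 0.54 (-0.06 to 1.38), and 0.05 against the other control. Smooth muscle minus blood in si-Fli1 was 0.53 (-0.48 to 1.52), and 0.64 (0.15 to 1.36) against the other control. In si-Sox18, smooth muscle minus pericyte was 1.20 (0.31 to 1.55), and 0.86 (-0.07 to 2.25) against the other control, over 5 and 4 pericyte genes. In si-Mix, smooth muscle minus blood was 0.83 (0.25 to 1.78), and 1.11 (-0.28 to 1.95) against the other control. Smooth muscle minus matrix and mesenchyme had intervals that include 0 in all 5 with either control, with si-Mix against si-control at 0.41 (-0.09 to 0.84) and 0.31 between the controls. A dependence of endothelial genes on the 4 factors, a change in the smooth muscle cells themselves, and variation between cultures stay open, since each condition has 1 array.

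Cardiac muscle genes were higher in si-Fli1 (median 0.61). A low cardiac signal on the si-control array is argued against by the median of 0.66 against the other control array, above all random lists. An effect of Fli1 knockdown and variation between cultures stay open, as does an effect of the siRNA on other transcripts; these were not tested. In si-Mix, which also received Fli1 siRNA and in which Fli1 was at -1.55, the cardiac median was 0.16, within the random lists.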
